A study of Arabidopsis thaliana with 31 samples.

How the data were processed

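RNA was sequenced from whole Arabidopsis thaliana seedlings grown for 12 days on soil under long days. The labels describe 2 experiments, whose values stand in separate tables and were never pooled. Experiment A holds Col-0 (2 libraries), gcn5-7 (3), arp6-1 (3) and the gcn5-7 arp6-1 double mutant (3). Experiment B holds Col-0, gcn5-7, the nrp1-1 nrp2-2 double mutant and the gcn5-7 nrp1-1 nrp2-2 triple mutant (5 libraries each). GCN5 is a histone acetyltransferase, ARP6 is a subunit of the SWR1 complex that deposits the histone variant H2A.Z, and NRP1 and NRP2 are histone chaperones. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

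Per the labels, the authors trimmed reads with fastp 0.23.4 and aligned them with HISAT2 2.2.1 to TAIR10. The deposited values are a signal that the authors computed as TPM scaled by TMM. The read counter, its handling of strand, the annotation and any filter are not given in the sources used here. Each of the 2 tables lists 32833 genes, of which 32548 matched the TAIR10 annotation used here. Column sums ran from 715741 to 2078175 in A and from 704073 to 1794259 in B, so the columns are not plain TPM. Read numbers were recovered by finding, for each library, the factor that turns value times exon length into whole numbers. Among values below 20 recovered reads, 98.4 to 99.5% in A and 99.4 to 99.6% in B lay within 0.05 of a whole number. Depth recovered in this way was 38.3 to 39.6 M reads per library in A and 10.4 to 16.8 M in B. No pair of replicates agreed within sampling noise, so the spread between libraries, not the counting of reads, sets the precision of group means.

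Each table was analysed as log2(value + 1), with a pseudocount of 1. Genes with a mean of at least 1 over all libraries of their table were tested, 18322 in A and 19507 in B. All groups of a table entered a single limma fit (R 4.3.3, limma 3.58.1) with a mean-variance trend and robust empirical Bayes, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Each mutant was compared with Col-0, each multiple mutant with its parents, and the interaction tested whether the multiple mutant departed from the sum of its parents' changes. Fold changes are log2 with their standard error, and means of deposited values carry the SD over libraries. Of 200 genes with simulated changes, A called 0 of 80 at 1 (log2), 10 of 60 at 2 and 54 of 60 at 4. B called 35, 52 and 60. False calls were 8.57% in A and 5.16% in B. Real libraries also differ by batch and replicate number, so these rates may not hold.

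A total of 26 gene lists was written before the data were examined: the 4 targeted genes, the FLC clade, flowering time, floral organ identity, the circadian clock, H2A.Z with SWR1 and INO80, histone acetylation, histone chaperones, salicylic acid defence, jasmonate, auxin response, cold and ABA, heat shock, light and shade signalling, light harvesting, flavonoids and anthocyanins, glucosinolates, iron homeostasis, phosphate starvation, cuticular wax, DNA damage, cell cycle, meristem, senescence, root markers, and seed and embryo genes. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Both adjusted p-values are given for each list call that the estimate ended. Calls of members are counted over all genes tested and adjusted over the list alone. A list of mitochondrial import genes and prohibitins and a list of mitochondrial dysfunction markers were added after seeing the data.

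Genes are named by a rule written at the same stage. It takes the targeted genes and the FLC clade in each comparison with Col-0. It adds the 8 highest and 8 lowest fold changes (5 and 5 between mutants and for interactions) among called genes that have a symbol, a mean of at least 5 in the higher group and, except for interactions, no overlap between libraries. From each list with at least 3 called members it takes the 3 with the smallest adjusted p. Any other gene is said to be chosen after its values were seen.

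A GCN5-responsive score was computed for each library of B as the mean log2(value + 1) of genes called in gcn5-7 against Col-0 in A with a log2 change of at least 1, minus the mean of those called with a change of -1 or lower. The score in A used genes chosen likewise in B. Exact permutation tests were 2-sided and ignored replicate pairs. Overlaps between mutants of a table share the Col-0 libraries, and were therefore also computed with the Col-0 libraries of B split between both comparisons in 20 ways. Replicate numbers were examined as possible pairs. In B each pair correlated above 0.1 after group means were removed for nrp1-1 nrp2-2 and triple mutant against Col-0 and for the triple mutant against both parents, and the value with a replicate block is given there where it changes a call or a count.

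Alternatives chosen before the data were examined were removal of organelle genes with rescaling of each library to the same sum, quantile normalization, leaving out each library, fitting only the groups compared, a mean of at least 5, no filter, a replicate block, pseudocounts of 0.1 and 5, plain empirical Bayes, the estimated correlation, and scores over all called genes. Alternatives added after seeing the data were a batch term in A or B, the first batch of A left out, replicates 1 and 2 or 3 to 5 of B alone, a correction for gene length (spline with 5 degrees of freedom), its combinations with block and batch, voom on recovered reads, and a score without 3 genes higher in gcn5-7 of B than in its other groups. MASS 7.3.60.0.1 was used for robust fits, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for the remaining steps. No library was left out.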

Results

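Transcript levels were measured by RNA sequencing in 31 libraries of 12-day-old Arabidopsis seedlings, as TMM-scaled TPM. Experiment A compared Col-0 (n = 2) with gcn5-7, arp6-1 and gcn5-7 arp6-1 (n = 3 each). Experiment B compared Col-0 with gcn5-7, with the NRP double mutant nrp1-1 nrp2-2 and with the triple mutant carrying all of these alleles (n = 5 each). The crosses ask how loss of H2A.Z deposition (arp6-1) or of a pair of histone chaperones (nrp1-1 nrp2-2) alters the transcriptome with and without GCN5. In A, replicate 1 of Col-0, gcn5-7 and arp6-1 stood apart on the first principal component, which held 68.2% of the variance, and are called the first batch. In B, replicates 1 and 2 had more chloroplast transcripts than replicates 3 to 5, at 0.669 and 0.386% of the signal against 0.0998 to 0.173% in Col-0, but 0.1351 and 0.1355% against 0.0966 to 0.12% in gcn5-7. Relative to each gene's mean, values also followed exon length to a degree that differed by library (Spearman's rho across genes).

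**Figure D1:**
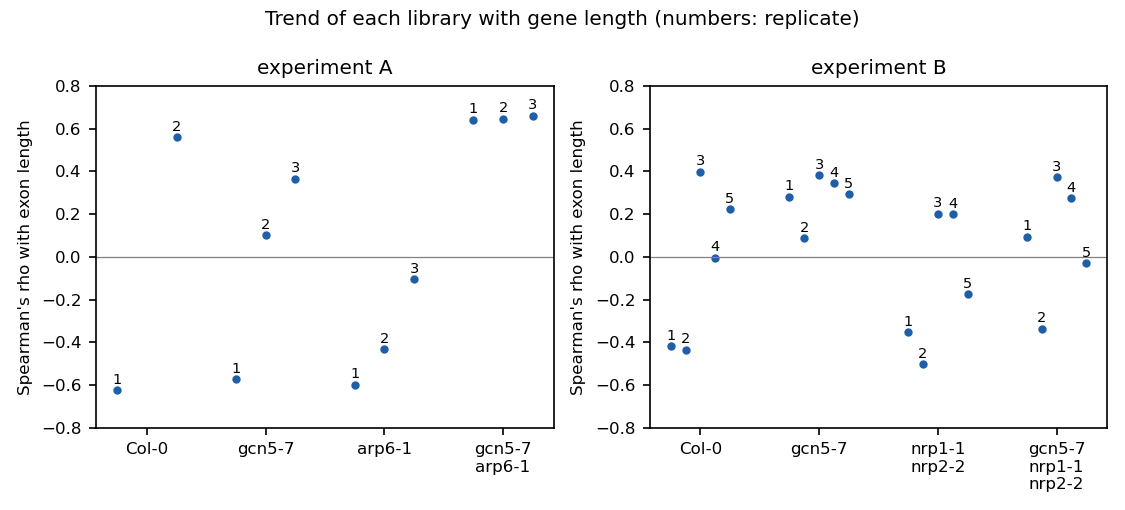
Spearman's rho across genes between exon length and level relative to the gene's mean in its table. Points are libraries numbered by replicate, for the 4 groups of A and B. The 3 double-mutant libraries of A lie at 0.642 to 0.661, above the other 8 of that experiment, the highest at 0.559.

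The mutated genes themselves gave a check of the genotypes. ARP6 (AT3G33520) was at 0.214 ± 0.133 TMM-scaled TPM (SD, n = 3) in arp6-1 and 0.514 ± 0.244 (n = 3) in gcn5-7 arp6-1, against 27.2 ± 12.6 (n = 2) in Col-0 of A. NRP2 (AT1G18800) was at 0.208 ± 0.195 (n = 5) in nrp1-1 nrp2-2 and was listed at 0 in all 5 triple-mutant libraries, against 11.8 ± 2.37 (n = 5) in Col-0 of B. NRP1 (AT1G74560) was reduced to 6.91 ± 2.01 in nrp1-1 nrp2-2 and 11.3 ± 1.37 in the triple mutant, against 27.8 ± 4.68 in Col-0. RNA of GCN5 (AT3G54610) was called in neither experiment in gcn5-7. It stood at 8.39 ± 3.05 against 6.74 ± 1.05 in A (adjusted p = 0.988), and at 4.44 ± 1.34 against 5.61 ± 1.45 in B (adjusted p = 0.33), so the gene-level RNA does not check that label. In gcn5-7 of B, NRP1 rose to 48.5 ± 6.92 (log2 fold change 0.78, adjusted p = 0.00538) and NRP2 to 23.9 ± 4.06 (0.96, adjusted p = 0.000893). ARP6 fell there from 18.4 ± 2.59 to 12.2 ± 1.98 (-0.56, adjusted p = 0.0428).

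**Figure D2:**
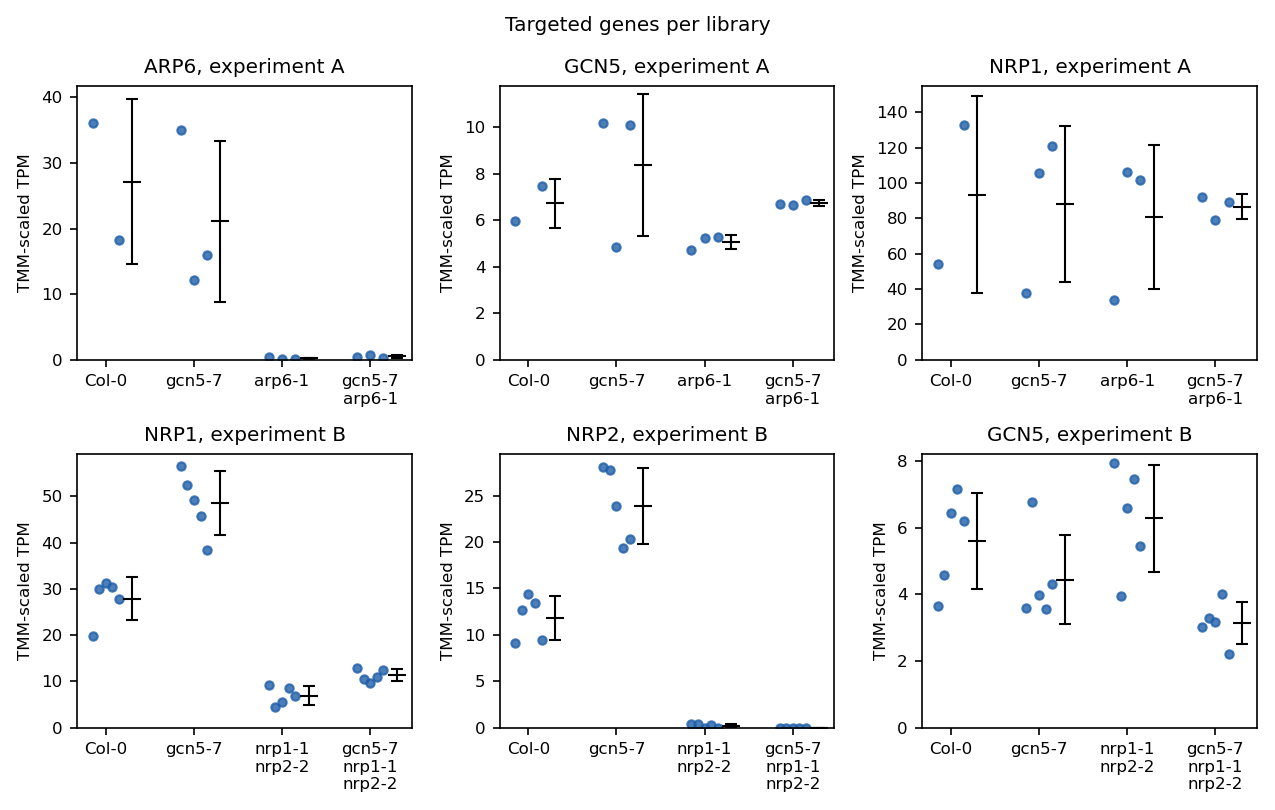
Levels in TMM-scaled TPM (linear axes) of the targeted genes, with points for libraries and bars for the mean and SD of each group. ARP6 is at 0.214 in arp6-1 and 27.2 in Col-0 of A, NRP2 at 0.208 in nrp1-1 nrp2-2 and 11.8 in Col-0 of B.

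The comparison of gcn5-7 with Col-0 in B asks which genes respond to the GCN5 mutation, and gave the most called genes among comparisons with Col-0. KTI1, a trypsin inhibitor, rose from 1.60 to 94.9 ± 85.4 (SD, n = 5; log2 fold change 4.65 ± 0.73 SE, adjusted p = 0.000287). NIT2, a nitrilase, rose from 4.73 to 98.7 (4.28, adjusted p = 0.000759), and OSM34, an osmotin, from 0.643 to 25.6 (3.74, adjusted p = 0.000109). SAG13, AIG1, TAT3, RLP41 and the chitinase gene AT2G43570 rose as well, by 3.42 to 4.14. EXLB1, an expansin-like gene (AT4G17030), fell from 29 to 0.0182 (-4.73 ± 0.36, adjusted p = 8.6e-08). ARGAH2, an arginase, fell from 82.3 to 7.95 (-3.23, adjusted p = 6.25e-08) and SCPL11, a serine carboxypeptidase-like gene, from 9.03 to 0.492 (-2.75, adjusted p = 8.6e-08). AGP41, PPT2, NHL12 and PAP3 fell by 2.59 to 3.25, with adjusted p from 2.23e-07 to 0.000287.

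Of the 24 measured salicylic acid defence genes, 16 rose and 0 fell over all genes tested (22 and 0 adjusted over the list alone), with a median log2 fold change of 2.07 (camera adjusted p = 1.24e-07). ALD1 rose from 1.04 to 21.7 (3.25, adjusted p = 0.00939). SARD1 rose from 9.0 to 47.8 (2.15), and CYP71A13 of camalexin synthesis from 6.99 to 55.7 (2.45). Of 24 light harvesting genes, 17 fell and 0 rose (20 and 0 adjusted over the list alone; median -1.20, camera adjusted p = 2.01e-08). LHCB1.4 fell from 1205 to 249 (-2.61), LHCB4.3 from 388 to 108 (-1.85) and RBCS3B from 18420 to 6494 (-1.52). Among 16 flavonoid and anthocyanin genes, 9 fell (11 adjusted over the list alone; median -0.86, camera adjusted p = 0.000105), including CHS from 528 to 252 (-1.07), MYB11 and TT19. With an estimated correlation the adjusted p was 0.375 for each of these 3 lists, which kept the sign of their medians under both other scalings.

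Histone acetylation genes rose as a list, with 5 of 14 called (8 adjusted over the list alone), a median of 0.85 and a camera adjusted p of 0.00276. HAG2, another acetyltransferase, rose from 9.91 to 19 (0.87, adjusted p = 0.00236). TRA1A and TRA1B rose by 1.42 and 1.11, and stood at 0.09 (adjusted p = 0.623) and -0.22 after the gene-length correction. In the H2A.Z, SWR1 and INO80 list, 3 of 15 rose (2 adjusted over the list alone; median 0.43, camera adjusted p = 0.0326). These were YAF9B, from 1.04 to 6.89 (1.93, adjusted p = 5.75e-05), RVB21 (0.93) and the SWR1 ATPase gene PIE1 (1.08, adjusted p = 0.0443; 0.08, adjusted p = 0.676 after the gene-length correction). DNA damage genes also rose, 5 of 11 by either count adjusted over the list alone or over all genes (median 0.66, camera adjusted p = 0.00873), with the regulator SOG1 up from 3.81 to 9.91 (1.21). RAD17 rose by 1.00. For these 3 lists the adjusted p was 0.375 with an estimated correlation. Of 11 histone chaperone genes, SPT16 (1.02) and SSRP1 (0.97), the subunits of FACT, rose (0 adjusted over the list alone; median 0.36, camera adjusted p = 0.133). Both are named after their values were seen.

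Hormone and stress lists moved in both directions in gcn5-7 of B. For jasmonate, 5 of 19 rose (5 adjusted over the list alone; median 0.58, camera adjusted p = 0.0481, and adjusted p = 0.509 with an estimated correlation), among them the repressor genes JAZ1, from 4.02 to 20.7 (2.06), and JAZ2 (0.95) and the activator gene ORA59 (1.58). Senescence genes rose, 4 of 8 (6 adjusted over the list alone; median 0.96, camera adjusted p = 0.0326, and adjusted p = 0.407 with an estimated correlation), with NAP up by 2.08 and PAO by 0.65. For auxin response, 2 of 17 rose and 6 fell (3 and 6 adjusted over the list alone; median -0.63, camera adjusted p = 0.0321, and adjusted p = 0.375 with an estimated correlation). The Aux/IAA repressor genes IAA7 and IAA17 fell by 1.33 and 1.4, and SAUR23 fell by 1.63. With gene length corrected, camera gave 0.0769 for jasmonate, 0.101 for auxin response and 0.0604 for the H2A.Z list. Among phosphate starvation genes, 3 of 12 fell (4 adjusted over the list alone; median -0.50, camera adjusted p = 0.0326, and adjusted p = 0.458 with an estimated correlation), including AT4 (-1.95), SQD2 and MGD2. For heat shock, 4 of 14 rose and 1 fell (7 and 2 adjusted over the list alone; median 0.77, camera adjusted p = 0.213), with HSP101 up by 1.68, HSP17.4 up by 1.24 and HSP18.2 down (-1.50). For cold and ABA, 0 of 10 were called by limma over all genes or adjusted over the list alone (median -0.43, camera adjusted p = 0.278).

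Of the 6 FLC clade genes, which encode repressors of flowering, MAF4 fell from 3.79 to 1.09 (-1.05 ± 0.30, adjusted p = 0.0177) and MAF2 rose from 6.58 to 11.1 (0.69, adjusted p = 0.0426), the latter at 0.22 (adjusted p = 0.339) after the gene-length correction. FLM, MAF3, MAF5 and FLC stood at -0.01, 0.29, -0.68 and -0.68 without being called (1 up and 1 down adjusted over the list alone; median -0.35, camera adjusted p = 0.625). In the flowering time list, 4 of 18 rose and 6 fell (4 and 9 adjusted over the list alone; median -0.49, camera adjusted p = 0.155). The florigen gene FT fell from 2.72 to 0.613 (-1.20, adjusted p = 0.0016), SPL4 by 1.35 and AGL24 by 0.99. Floral organ identity genes fell in 2 of 5 cases by either count, FUL (-1.15) and SEP4 (-1.69), named after their values were seen (2 adjusted over the list alone; median -0.62, camera adjusted p = 0.0241, and adjusted p = 0.375 with an estimated correlation). In the meristem list, KNAT1 rose (0.96) and CLV1 and AS2 fell (-1.02 and -0.81), with the same counts adjusted over the list alone, and the median of -0.08 over 9 genes stood at 0.29 with libraries rescaled to equal sums without organelle genes, called equal sums below (camera adjusted p = 0.479). Cuticular wax genes fell, 3 of 14 (3 adjusted over the list alone; camera adjusted p = 0.0241, and adjusted p = 0.375 with an estimated correlation), with CER2 at -1.17, CER26 at -0.67 and WSD1 at -2.09, and a median of -0.39 that stood at 0.01 with equal sums.

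In the remaining lists of this comparison camera called nothing. Cell cycle genes included 3 that rose, with CDT1A at 1.17 and MCM7 at 0.68, and CYCD3;1 that fell (-0.69), of 23 measured (0 adjusted over the list alone; median 0.07, and -0.09 with quantile normalization; camera adjusted p = 0.479). Of 14 clock genes, PRR7 rose (1.93) and LUX fell (-1.16), both also adjusted over the list alone (median 0.27, camera adjusted p = 0.447). In the glucosinolate list of 16, the regulators MYB29, from 14 to 3.69 (-1.71), and MYB28 (-1.16) were among 4 that fell and CYP79F2 (1.12) among 2 that rose, with the same counts adjusted over the list alone (median -0.23, and 0.17 with equal sums; camera adjusted p = 0.433). Of 17 iron homeostasis genes, 6 fell and 1 rose (6 and 2 adjusted over the list alone; median -0.22, and 0.08 with equal sums; camera adjusted p = 0.145), with nicotianamine synthase NAS1 down from 36.2 to 8.40 (-2.04), ferritin FER4 down (-1.20) and FRD3 up (0.95). Light and shade signalling had 2 genes that fell of 10, ELIP2 (-1.82) and XTH15 (-1.0), by the count over all genes and adjusted over the list alone, with a median of 0.01 where camera pointed down (adjusted p = 0.669). Of 2 measured root markers PYK10 rose (1.25) by both counts, adjusted over the list alone or over all genes, and the 1 measured seed and embryo gene was not called by either. ELIP2, XTH15, PRR7, LUX and PYK10 are named after their values were seen.

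In total 5118 of 19507 genes were called in gcn5-7 of B, 2254 higher and 2864 lower. With equal sums the split was 4646 higher and 1521 lower, since that scaling moves the median of all genes by 0.355. The count was 3282 without Col-0 replicate 1, 3315 without Col-0 replicate 2, 2949 without gcn5-7 replicate 1 and 3356 without gcn5-7 replicate 3.

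The same mutant was compared with Col-0 in A. GSTU3 rose from 0.71 to 31.1 ± 11.4 (SD, n = 3; log2 fold change 4.17 ± 0.55, adjusted p = 0.0211). PHT3;2 rose from 1.24 to 16.3 (2.88, adjusted p = 0.0455), ADS4 from 2.59 to 21.4 (2.71, adjusted p = 0.0463) and UMAMIT37 from 0.72 to 6.63 (2.12, adjusted p = 0.0152). EXLB1 fell from 55.7 to 0.0433 (-5.69 ± 0.41, adjusted p = 0.000451), SCPL11 from 9.43 to 0.448 (-2.85, adjusted p = 0.0104) and PAP3 fell to 2.13 (-2.73, adjusted p = 0.0455). All 7 passed in gcn5-7 of B in the same direction. No gene of the FLC clade was called in A, where MAF4 stood at -0.32, MAF5 at 0.77 (adjusted p = 0.422), MAF2 at 0.35, MAF3 at 0.04 and FLM at 0.20. FLC was below the mean required for a test.

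Salicylic acid defence was again higher as a list in gcn5-7 of A, with a median of 1.42 over 25 genes (camera adjusted p = 2.86e-14, and adjusted p = 0.347 with an estimated correlation), although 0 members were called over all genes by limma (8 adjusted over the list alone). Light harvesting was lower (median -0.84, camera adjusted p = 6.36e-07), as was auxin response (-0.93, camera adjusted p = 0.0021), while jasmonate (0.60, camera adjusted p = 0.00748) and senescence (0.81, camera adjusted p = 0.0339, and 0.0727 after the gene-length correction) were higher and wax was lower (-0.33, camera adjusted p = 0.0339). For these lists the adjusted p was 0.581 with an estimated correlation, and adjusted over the list alone 1 senescence gene and none of the others was called. Without Col-0 replicate 1 light harvesting stood at -0.23 and auxin response at 0.02 (adjusted p = 0.527 each). Floral organ identity was lower (median -1.08, camera adjusted p = 0.000241, and adjusted p = 0.235 with an estimated correlation; 2 lower adjusted over the list alone). Over the 17451 genes tested in both experiments the fold changes of gcn5-7 correlated with r = 0.731 and rho = 0.656 across genes, which are not independent replicates. All 21 genes called in A and tested in B were called in B in the same direction, 9 higher and 12 lower, against 1.05 and 1.82 expected by chance.

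In A the limma test called 26 genes in gcn5-7, 13 higher and 13 lower, with 1561 at an unadjusted p under 0.05. The count was 1468 with a batch term for the first batch and 0 with only the groups compared. It was 6 without Col-0 replicate 1, 90 without Col-0 replicate 2, and 5, 3 and 45 without gcn5-7 replicates 1, 2 and 3.

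**Figure D3:**
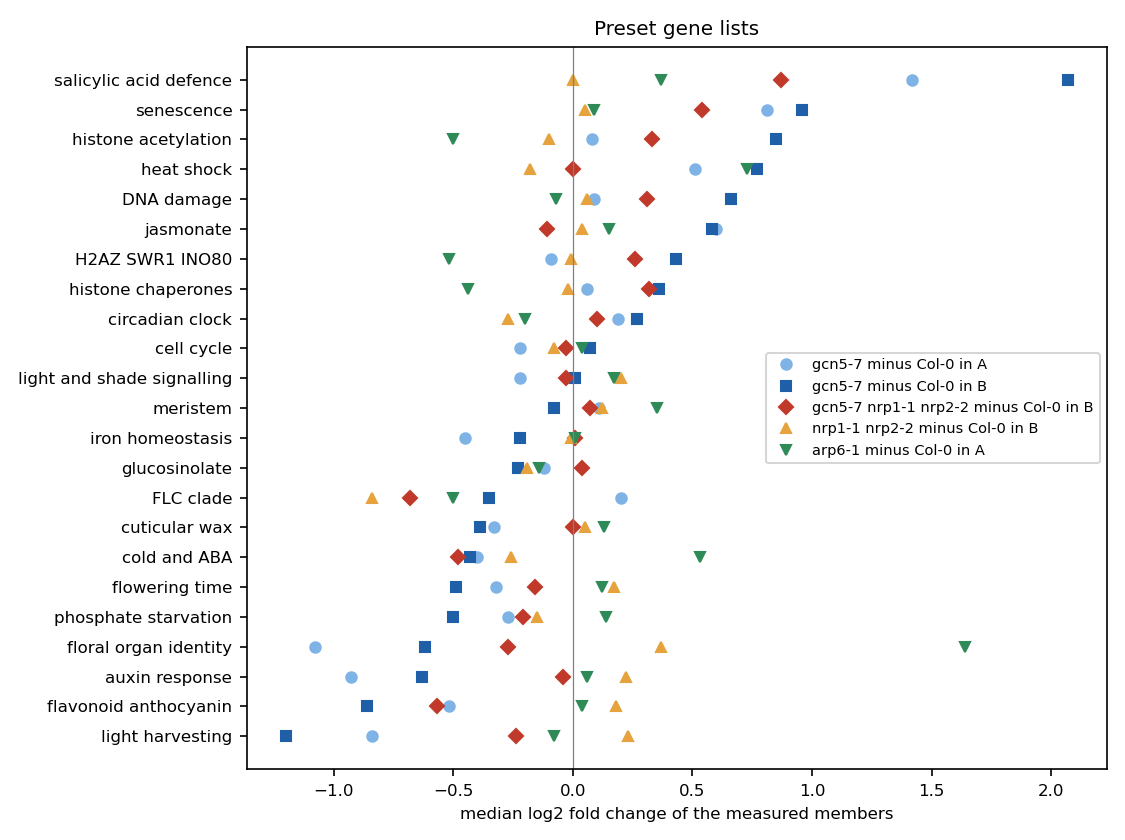
Median log2 fold change against Col-0 of the measured members of 23 gene lists, with 1 point per list for gcn5-7 in A and B, the triple mutant and nrp1-1 nrp2-2 in B, and arp6-1 in A. Salicylic acid defence lies at 2.07 and 1.42 in gcn5-7 of B and A and at 0.87 in the triple mutant, light harvesting at -1.20, -0.84 and -0.24.

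The comparison of arp6-1 with Col-0 asks which transcripts respond to loss of SWR1 function. Besides ARP6 itself (-4.46 ± 0.47, adjusted p = 0.0133), MAP1B fell from 8.94 to 0.435 (-2.79 ± 0.30, n = 3 against 2, adjusted p = 0.0133). AT3G06955, named after its values were seen, fell from 89.7 to 0.698 (-5.33 ± 0.65, adjusted p = 0.035). The FLC clade was lower as a list, with a median of -0.50 over 5 genes and 2 adjusted over the list alone against 0 over all genes (camera adjusted p = 5.34e-06, and adjusted p = 0.0171 with an estimated correlation). MAF4 was at 0.362 against 2.9 in Col-0 (-1.46, adjusted p = 0.727, and 0.0191 with the batch term) and MAF5 at 0.324 against 2.42 (-1.37, adjusted p = 0.37, and 0.0117 with the batch term). MAF2, MAF3 and FLM stood at -0.50, -0.29 and -0.07. Floral organ identity genes were higher as a list (median 1.64 over 5 genes, 3 adjusted over the list alone, camera adjusted p = 5.78e-09, and adjusted p = 0.0171 with an estimated correlation). SEP3 was at 10.6 against 1.24, SEP1 at 8.33 against 1.83 and FUL at 44.6 against 14.1, none of them called over all genes and all named after their values were seen.

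Heat shock genes were higher in arp6-1 (median 0.73, 2 adjusted over the list alone, camera adjusted p = 3.46e-07, and adjusted p = 0.0703 with an estimated correlation). The H2A.Z, SWR1 and INO80 list was lower (median -0.52, camera adjusted p = 0.00179, and adjusted p = 0.164 with an estimated correlation), as was histone acetylation (-0.50, camera adjusted p = 0.00431, and adjusted p = 0.566 with an estimated correlation). The latter held no longer after the gene-length correction (adjusted p = 0.33), and fold changes in arp6-1 correlated with exon length at rho = -0.42 across genes. Salicylic acid defence (median 0.37, camera adjusted p = 8.5e-05), cold and ABA (0.53, camera adjusted p = 0.00431) and wax (0.13, camera adjusted p = 0.0423) were higher, each with an adjusted p = 0.544 with an estimated correlation. Meristem genes were also higher (0.35, camera adjusted p = 0.0085, and adjusted p = 0.164 with an estimated correlation). Without Col-0 replicate 2 the H2A.Z list stood at 0.05 and acetylation at 0.17 (adjusted p = 0.402 each). Defence stood at -0.03 (adjusted p = 0.704) without Col-0 replicate 1 and 0.12 (adjusted p = 0.163) without arp6-1 replicate 3. In these 6 lists 0 members were called by limma over all genes or adjusted over the list alone.

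In arp6-1 the limma test called 3 genes, all lower, with 333 at an unadjusted p under 0.05. The batch term gave 161, leaving out Col-0 replicate 2 gave 9, and leaving out Col-0 replicate 1 or any arp6-1 replicate gave 0.

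In the gcn5-7 arp6-1 double mutant against Col-0, which asks for the joint effect of both mutations, GOLS2, a galactinol synthase gene, rose from 0.847 to 55.8 (log2 fold change 4.81 ± 0.51, n = 3 against 2, adjusted p = 0.00305), RD29B from 0.043 to 21.2 (4.25 ± 0.42, adjusted p = 0.00251) and P5CS1 of proline synthesis from 10.3 to 255 (4.38, adjusted p = 0.037). PUB19, HB-7, AFP1 and TSPO rose by 3.5 to 3.77, and AGO5 from 0.0415 to 11.9 (3.63, adjusted p = 0.00251). QQS fell from 23.3 to 0.788 (-3.57, adjusted p = 0.0113), and the flowering gene AGL24 from 70.5 to 5.38 (-3.45, adjusted p = 0.0245). EXO and TCH4 fell from 73.7 to 6.16 (-3.28) and from 37.7 to 4.08 (-2.94), and SDR2 fell by 2.95. MEE3 (-3.25) and BT5 (-3.20) fell too, with adjusted p = 0.0574 and 0.0737 after the gene-length correction. ARP6 fell by 4.15, while GCN5, NRP1 and NRP2 stood at 0.01, 0.03 and -0.09. MAF5 fell from 2.42 to 0.105 (-1.62, adjusted p = 0.0222), MAF4 was at 0.258 (-1.57, adjusted p = 0.0546), and FLM, MAF3 and MAF2 stood at -0.47, 0.14 and 0.53.

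Among lists, DNA damage genes rose in the double mutant, 3 of 13 (5 adjusted over the list alone; median 1.17, camera adjusted p = 0.00199), with PARP2 up from 0.744 to 6.71 (2.17) and ANAC044 up to 10.6 (2.49). GMI1 rose from 0.255 to 5.94 (2.47, adjusted p = 0.00305), and stood at 0.99 (adjusted p = 0.147) after the gene-length correction. Histone acetylation was higher, with HAC1 called at 2.29 (7 adjusted over the list alone; median 1.33, camera adjusted p = 0.00134, and 0.137 after the gene-length correction). Cold and ABA had 2 of 13 called, GOLS2 and RD29B (4 adjusted over the list alone; median 0.42, camera adjusted p = 0.0632, and 0.00205 after the gene-length correction). Light harvesting was lower (median -1.0, 0 called and 0 adjusted over the list alone, camera adjusted p = 0.000366), and PYK10, the 1 measured root marker, stood at 1.75 without being called. Auxin response (median -0.96) and flavonoids (-1.05) were lower and wax (0.92, CER1 called at 2.48) and heat shock (1.11, HSP70B called at 1.57) were higher, each with a camera adjusted p = 0.0291. With gene length corrected it was 0.356 for auxin, 0.11 for flavonoids and 0.15 for wax. Auxin stood at 0.18 (adjusted p = 0.637) without Col-0 replicate 1. Adjusted over the list alone, 0 auxin and flavonoid genes, 2 wax genes and 4 heat shock genes passed. Each of these lists had an adjusted p = 0.658 with an estimated correlation. HAC1, CER1 and HSP70B were chosen after their values were seen.

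With limma, 378 genes were called in the double mutant, 309 higher and 69 lower. Fold changes correlated with exon length at rho = 0.65 across genes. The split was 531 and 280 with quantile normalization, and equal sums moved the median of all genes by 0.59. The count was 17 without Col-0 replicate 1, 7216 without Col-0 replicate 2, and 129, 17 and 43 without double-mutant replicates 1, 2 and 3.

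Compared with its gcn5-7 parent, which asks what loss of ARP6 changes where GCN5 is mutated, EXLB1 rose from 0.0433 to 19.8 (4.3 ± 0.37, n = 3 each, adjusted p = 0.000407), SCPL11 from 0.448 to 8.17 (2.66, adjusted p = 0.000962) and PAP3 rose from 2.13 (2.44, adjusted p = 0.00442). GSTU3 fell from 31.1 to 2.23 (-3.48, adjusted p = 0.00296), UMAMIT37 from 6.63 to 0.329 (-2.5, adjusted p = 0.000437), ADS4 from 21.4 to 3.39 (-2.37) and PHT3;2 from 16.3 to 3.22 (-2.02). These 7 genes were chosen with the same gcn5-7 libraries. By fold change, GOLS2 (5.07), FMO GS-OX2 from 0.312 to 34.3 (4.60), RD20 (4.53), WSD1 from 1.02 to 50.2 (4.47) and P5CS1 (4.32) rose most. The plant defensin genes PDF1.2c (-5.56, adjusted p = 0.0286), PDF1.2b (-5.11) and PDF1.2 (-4.37), and PHI-1 (-4.77) and EXO (-4.16, adjusted p = 0.000407) fell most.

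In the double mutant against gcn5-7, jasmonate genes fell, 8 of 21 with 1 rising (11 and 2 adjusted over the list alone; median -1.45, camera adjusted p = 0.000978), including AOS (-2.10) and JAZ8 (-2.02). Salicylic acid defence fell, 5 of 25 (7 adjusted over the list alone; median -0.73, camera adjusted p = 0.000978), including CYP71A13 (-3.50) and WRKY54 (-2.53). Wax genes rose, 5 of 14 (7 adjusted over the list alone; median 1.25, camera adjusted p = 0.00207), with CER1 at 3.20. DNA damage rose in 5 of 13 (6 adjusted over the list alone; median 0.74, camera adjusted p = 0.00677). Cold and ABA genes rose in 6 of 13 (6 adjusted over the list alone; median 0.61, camera adjusted p = 0.00861) with RD29A at 3.61, and phosphate starvation genes in 4 of 14 (6 adjusted over the list alone; median 1.06, camera adjusted p = 0.0174). Each of these 6 lists had an adjusted p = 0.552 with an estimated correlation. Floral organ identity rose in 3 of 5 (5 adjusted over the list alone; median 1.67, camera adjusted p = 0.00166, and adjusted p = 0.401 with an estimated correlation), SEP1 by 2.5, SEP3 by 3.3 and SEP4 by 1.57. In the FLC clade MAF4 and MAF5 fell by 1.26 and 2.39 (2 adjusted over the list alone; median -0.67, camera adjusted p = 0.0385, and adjusted p = 0.492 with an estimated correlation). Histone acetylation rose in 7 of 13 (7 higher and 1 lower adjusted over the list alone; median 1.25, camera adjusted p = 0.01, and adjusted p = 0.625 with an estimated correlation), and had a camera adjusted p = 0.689 after the gene-length correction. Their named members were chosen after their values were seen.

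Against gcn5-7, limma called 2504 genes, 1793 higher and 711 lower, with rho = 0.58 between fold change and exon length across genes. The split was 2129 and 1716 with quantile normalization and 1379 and 594 with equal sums, which moved the median of all genes by 0.302. The count was 862 and 1285 without gcn5-7 replicates 1 and 2, and 1200, 414 and 677 without double-mutant replicates 1, 2 and 3.

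Compared with arp6-1, which asks what the GCN5 mutation changes where ARP6 is lost, P5CS1 (4.25, adjusted p = 0.00885), NET1D from 0.414 to 20.7 (3.78, adjusted p = 0.00159), RD29B (3.72, adjusted p = 0.00126) and HB-7 (3.54) rose most. PPI1 rose from 5.74 to 60 (3.66, adjusted p = 0.0439, and 0.0633 after the gene-length correction). PHI-1 (-4.17), FTM1 from 49 to 1.36 (-3.89, adjusted p = 0.00747), AT7SL-1 (-3.84), LSH10 from 138 to 8.46 (-3.74) and SWEET10 from 32.4 to 0.471 (-3.66, adjusted p = 0.0247) fell most. Histone acetylation genes rose, 7 of 13 (9 adjusted over the list alone; median 1.9, camera adjusted p = 0.000642, and 0.156 after the gene-length correction). DNA damage genes rose, 5 of 13 (8 higher and 1 lower adjusted over the list alone; median 1.4, camera adjusted p = 0.00532, and 0.0921 after that correction). Light harvesting was lower at a median of -0.78 that stood at 0.04 with equal sums and 0.18 with quantile normalization (camera adjusted p = 0.00532, and 0.243 after the length correction). All 3 lists had an adjusted p = 0.782 with an estimated correlation. In all, limma called 2715 genes, 2173 higher and 542 lower, with rho = 0.69 between fold change and length across genes, against 2422 and 280 with equal sums (median of all genes moved by 0.672) and 2734 and 1928 with quantile normalization. The count was 653 and 578 without arp6-1 replicates 1 and 2, and 913, 313 and 425 without double-mutant replicates 1, 2 and 3.

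The interaction in A asks whether the double mutant departs from the sum of its parents' changes. ATSPS4F departed upward by 4.43 ± 0.91 (adjusted p = 0.0449), and so did SS4 (4.38), CFM3A (4.36), ZW9 (4.06) and FMO GS-OX2 (3.88). EXO departed downward by -4.50 (adjusted p = 0.0217), with ARD3 at -4.11 and TCH4 at -3.76. As lists, salicylic acid defence (median -1.52, camera adjusted p = 3.11e-05) and jasmonate (-1.41, camera adjusted p = 0.00326) were below the sum and histone acetylation (1.81, camera adjusted p = 0.00326), DNA damage (1.05, camera adjusted p = 0.0126) and wax (1.06, camera adjusted p = 0.0415) above it, each with an adjusted p = 0.72 with an estimated correlation. With gene length corrected camera gave 0.416 for acetylation, 0.0715 for DNA damage and 0.13 for wax. Adjusted over the list alone, 0 defence and 0 jasmonate genes, 7 acetylation, 4 DNA damage and 4 wax genes passed, against 0, 0, 0, 2 and 0 over all genes. For the interaction limma called 252 genes, 230 higher and 22 lower, against 36 and 3 with equal sums (median of all genes moved by 0.378) and 597 and 177 with quantile normalization. The count was 2980 and 2 without Col-0 replicates 1 and 2, 3, 0 and 389 without gcn5-7 replicates 1 to 3, 0 without any arp6-1 replicate, and 94, 0 and 0 without double-mutant replicates 1 to 3.

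The comparison of nrp1-1 nrp2-2 with Col-0 in B asks which genes respond to loss of the NRP chaperones. Genes for mitochondrial proteins were among those that rose. PHB1 and PHB4, which encode prohibitins of the inner mitochondrial membrane, rose from 12.3 to 32.5 (1.34 ± 0.16, n = 5 each, adjusted p = 0.000151) and from 13 to 42.4 (1.58, adjusted p = 0.00841). MEE67 rose from 2.83 to 11.1 (1.65, adjusted p = 0.005) and DIC2 from 7.52 to 30.1 (1.89 ± 0.31, adjusted p = 0.00608). STZ rose from 8.44 to 35.4 (1.90, adjusted p = 0.0282), TEM2 from 4.36 to 18 (1.73, adjusted p = 0.0488), SWEET10 from 1.28 to 7.09 (1.68) and LBD37 from 12.1 to 34.3 (1.51). NRP2 (-3.40 ± 0.17, adjusted p = 2.63e-10), NRP1 (-1.89 ± 0.18, adjusted p = 1.1e-05) and CBL10 (-0.92, adjusted p = 0.0323) fell, while GCN5 and ARP6 stood at 0.14 and 0.03.

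The FLC clade was lower as a list in nrp1-1 nrp2-2, with 0 of 6 called over all genes and 5 adjusted over the list alone (median -0.84, camera adjusted p = 1.18e-06, and adjusted p = 0.00616 with an estimated correlation). FLC (AT5G10140) was at 0.88 ± 0.69 against 4.54 ± 2.37 in Col-0 (-1.53, adjusted p = 0.125, and 0.0236 with the replicate block). MAF4 was at 1.35 against 3.79 (-0.96, adjusted p = 0.36), with MAF5, MAF2, FLM and MAF3 at -0.92, -0.75, -0.45 and -0.20. Flowering time genes were higher (median 0.17, 1 called and 2 adjusted over the list alone, camera adjusted p = 0.0336), and clock genes lower (-0.27, 0 called and 2 adjusted over the list alone, camera adjusted p = 0.0336), both with an adjusted p = 0.29 with an estimated correlation. Floral organ identity was higher at a median of 0.37 that stood at -0.02 with equal sums (camera adjusted p = 0.0361, and adjusted p = 0.431 with an estimated correlation). Its 1 called gene over all genes and adjusted over the list alone was SEP3 (1.33), named after its values were seen. Auxin response was higher (0.22, camera adjusted p = 0.00962, and adjusted p = 0.399 with an estimated correlation), and so was light harvesting (0.23, camera adjusted p = 0.00962, and adjusted p = 0.863 with an estimated correlation). Glucosinolates were lower (-0.19, camera adjusted p = 0.0336, and adjusted p = 0.858 with an estimated correlation). Without nrp1-1 nrp2-2 replicate 2 light harvesting stood at -0.03 (adjusted p = 0.782) and clock genes at 0.00 (adjusted p = 0.105), and glucosinolates at 0.01 (adjusted p = 0.424) without Col-0 replicate 1. No auxin response, light harvesting or glucosinolate gene was called by either count. Salicylic acid defence had a median of 0.00 (camera adjusted p = 0.651), and of 0.32 without Col-0 replicate 3 (adjusted p = 0.0269). With replicates paired by a replicate block, the camera adjusted p was 0.0517 for flowering time and 0.111 for each of the clock, floral organ identity and glucosinolate lists. With gene length corrected these 3 had 0.188, 0.0645 and 0.0644.

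By limma, 76 genes were called in nrp1-1 nrp2-2, 58 higher and 18 lower, and 334 with replicates paired by a replicate block. It called 21 and 9 with equal sums, which moved the median of all genes by -0.134. The count was 36 and 44 without Col-0 replicates 3 and 5, and 36, 121 and 46 without nrp1-1 nrp2-2 replicates 1, 2 and 5.

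In the triple mutant against Col-0, which asks for the joint effect of the GCN5 and NRP mutations, NIT2 rose to 45.2 (3.08, adjusted p = 0.03), KTI1 to 23.4 (2.96, adjusted p = 0.0327) and OSM34 to 9.98 (2.58, adjusted p = 0.00845), and EXLB1 fell from 29 to 1.4 (-3.54, n = 5 each, adjusted p = 1.68e-05). MRD1 rose from 0.281 to 8.0 (2.53, adjusted p = 0.00327), OXS3 from 4.35 to 29 (2.34, adjusted p = 0.00497), TEM2 from 4.36 to 28 (2.32, adjusted p = 0.00129), and HSPRO2 and BT5 by 2.42 and 2.37. The cell wall genes XTH17 (-1.87) and XTH31 from 38.2 to 10.7 (-1.84), TLL1 from 79.8 to 20.4 (-1.90), ZW9 from 18.6 to 3.49 (-2.15, adjusted p = 0.000196) and both near-identical AT14A loci, AT3G28290 (-1.88) and AT3G28300 (-1.82), fell. NRP1 fell by 1.21 (adjusted p = 0.000681), and NRP2 was listed at 0. GCN5 stood at -0.66 (adjusted p = 0.133, and 0.0296 after the gene-length correction). In the FLC clade MAF5 fell from 6.27 to 1.54 (-1.37, adjusted p = 0.0365). FLC stood at -1.16 (adjusted p = 0.149, and 0.0359 with the replicate block) and MAF4 at -1.01 (adjusted p = 0.0969, and 0.0195 with the replicate block), with FLM, MAF2 and MAF3 at -0.36, -0.13 and -0.12.

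As lists in the triple mutant, salicylic acid defence was higher (median 0.87, camera adjusted p = 0.0013, and adjusted p = 0.768 with an estimated correlation; 0 called by limma over all genes or adjusted over the list alone). Without triple-mutant replicate 3 the median was 0.36 (adjusted p = 0.212), and without replicate 3 of each group 0.59 (adjusted p = 0.00111). The FLC clade was lower (median -0.68, 1 called and 3 adjusted over the list alone, camera adjusted p = 0.0013), as was cold and ABA (-0.48, 0 called and 5 adjusted over the list alone, camera adjusted p = 0.00247), both with an adjusted p = 0.076 with an estimated correlation. Flavonoids were lower (-0.57, MYB11 called by either count, adjusted over the list alone too, camera adjusted p = 0.0013, and adjusted p = 0.468 with an estimated correlation). DNA damage (0.31, 0 called by limma and 0 adjusted over the list alone, camera adjusted p = 0.0163) and the H2A.Z, SWR1 and INO80 list (0.26, YAF9B called and 2 adjusted over the list alone, camera adjusted p = 0.0317) were higher, both with an adjusted p = 0.355 with an estimated correlation. Light harvesting was lower (-0.24, camera adjusted p = 0.0345, and adjusted p = 0.903 with an estimated correlation). Without Col-0 replicate 1 it stood at -0.07 (adjusted p = 0.5). After the gene-length correction camera gave it 0.0893 and the H2A.Z list 0.0665. With the replicate block, 3 defence genes rose and 5 cold and ABA genes, 3 genes of the FLC clade and 2 flavonoid genes fell, and histone acetylation passed as a list (camera adjusted p = 0.11 without it and 0.0468 with it). In the triple mutant limma called 474 genes, 249 higher and 225 lower, and 1787 with replicates paired by a replicate block, and no single left-out library moved the count beyond 1.5 times. Equal sums moved the median of all genes by 0.106.

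Compared with gcn5-7, which asks what the NRP mutations change where GCN5 is mutated, ARGAH2 rose from 7.95 to 29.9 (1.80, adjusted p = 0.000323), and PGL34 from 4.1 to 18.1 (1.92, adjusted p = 1.19e-05). OXS3 rose from 4.56 to 29 (2.32, adjusted p = 0.0087), MRD1 by 2.11, and TOM7-2 from 2.69 to 13.6 (1.99, adjusted p = 0.0166). JAL34 fell from 30.5 to 6.0 (-2.13, adjusted p = 2.8e-05), NAI2 from 26.2 to 4.8 (-2.44, adjusted p = 0.0101), EARLI1 from 48.5 to 6.68 (-2.49, adjusted p = 0.0351) and MIR864 by 2.24. SCPL11 rose from 0.492 to 2.31 (1.09, adjusted p = 0.00828) and PAP3 from 1.97 to 5.58 (1.22, adjusted p = 0.0161). Light harvesting rose as a list, with 3 of 24 called and 15 adjusted over the list alone (median 0.90, camera adjusted p = 1.29e-09), LHCB4.3 from 108 to 230.2 (1.14, adjusted p = 0.0363) among them. Salicylic acid defence was lower, with 0 called by limma over all genes or adjusted over the list alone (median -1.10, camera adjusted p = 1.04e-05, and -1.67 without replicate 3 of each group). Both lists had an adjusted p = 0.34 with an estimated correlation. With the replicate block 21 light harvesting genes rose and 11 defence genes fell over all genes tested.

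Wax (median 0.33, 1 called and 3 adjusted over the list alone) was higher, and heat shock (-0.67), histone acetylation (-0.62) and jasmonate (-0.52, 5 lower adjusted over the list alone) lower, each with a camera adjusted p = 0.0055, and acetylation with 0.0748 after the gene-length correction. That correction also gave 0.0748 for flavonoids, 0.142 for auxin response and 0.0722 for the FLC clade. Flavonoids were higher (0.46, 5 adjusted over the list alone, camera adjusted p = 0.0156), as was iron homeostasis (0.38, 2 called and 5 adjusted over the list alone, camera adjusted p = 0.0203, and adjusted p = 0.308 with an estimated correlation). Flowering time (0.35, FT called at 0.86 and 3 adjusted over the list alone, camera adjusted p = 0.0464) and auxin response (0.46, 1 lower called and 2 higher with 1 lower adjusted over the list alone, camera adjusted p = 0.0469) were higher too. The FLC clade was lower (-0.45, camera adjusted p = 0.0222). Apart from iron, each of these lists had an adjusted p = 0.34 with an estimated correlation. With the replicate block 5 wax, 6 flavonoid, 6 iron, 5 flowering time and 8 auxin response genes rose, and 8 heat shock, 7 histone acetylation and 5 jasmonate genes fell. The FLC clade had a camera adjusted p = 0.0538 with that block, and floral organ identity one of 0.0451 (0.0516 without it). The limma test called 627 genes, 405 higher and 222 lower, and 4953 with replicates paired by a replicate block. With equal sums the split was 179 and 312 (median of all genes moved by -0.25). The count was 210, 354, 244, 941 and 318 without gcn5-7 replicates 1 to 5, and 263, 285, 1652, 331 and 183 without triple-mutant replicates 1 to 5.

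Compared with nrp1-1 nrp2-2, which asks what the GCN5 mutation changes where the NRP genes are mutated, OSM34 rose from 0.526 to 9.98 (2.72, adjusted p = 0.0122), CYP79F2 by 1.05 and MAKR6 by 0.97. XYL4 rose by 0.99 (adjusted p = 0.0489), and stood at 0.68 (adjusted p = 0.313) after the gene-length correction. PDF1.3 fell from 103 to 9.10 (-3.68, adjusted p = 0.00498), EXLB1 from 27.4 to 1.4 (-3.42, adjusted p = 4.02e-05), AGP41 from 47.5 to 5.55 (-2.58), SAG29 by 2.35 and CPL3 by 2.22. Flavonoids (median -0.53, 0 called and 3 adjusted over the list alone, camera adjusted p = 4.13e-06, and adjusted p = 0.17 with an estimated correlation) and light harvesting (-0.50, camera adjusted p = 5.57e-06, and adjusted p = 0.515 with an estimated correlation) were lower. So were auxin response (-0.36, camera adjusted p = 0.000195), floral organ identity (-0.65, with FUL and SEP3 called at -0.94 and -1.41 and the same 2 adjusted over the list alone, camera adjusted p = 0.000366) and cold and ABA (-0.37, 2 adjusted over the list alone, camera adjusted p = 0.00388), each with an adjusted p = 0.167 with an estimated correlation. Salicylic acid defence was higher (0.76, camera adjusted p = 0.00293, and adjusted p = 0.709 with an estimated correlation), at 0.26 (adjusted p = 0.373) without triple-mutant replicate 3 and 0.69 without replicate 3 of each group. With the replicate block 5 auxin response, 4 flavonoid, 3 floral organ identity and 3 cold and ABA genes fell and 2 defence genes rose. The limma test called 139 genes, 20 higher and 119 lower, and 1237 with replicates paired by a replicate block, against 26 and 67 with equal sums (median of all genes moved by 0.235). The count was 90 without triple-mutant replicate 1 and 92 without nrp1-1 nrp2-2 replicate 1.

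The interaction in B asks whether the triple mutant departs from the sum of its parents' changes. PGL34 departed upward by 1.98 ± 0.27 (adjusted p = 0.00447) and FUC1 by 1.70 ± 0.28 (adjusted p = 0.0159). Of the other genes called, named after their values were seen, AT1G68260 (1.48) and AT2G40960 (2.25) departed upward and AT1G64795 (-6.95, adjusted p = 4.58e-08), AT1G75945 (-4.08), AT2G11405 (-2.54) and AT2G41780 (-1.79) downward. As lists, salicylic acid defence (median -1.04, camera adjusted p = 7e-07), jasmonate (-0.50, 0.000123), histone acetylation (-0.56, 0.00403), senescence (-0.75, 0.00628), DNA damage (-0.31, 0.0124) and heat shock (-0.52, 0.0198) lay below the sum, and light harvesting (0.68, 1.67e-05) and glucosinolates (0.47, 0.0124) above it, each with an adjusted p = 0.531 with an estimated correlation. After the gene-length correction acetylation had 0.0631. Iron homeostasis also lay above it (0.34, camera adjusted p = 0.0251, and adjusted p = 0.39 with an estimated correlation). The limma test called 8 genes, 4 higher and 4 lower, with 1406 at an unadjusted p under 0.05, 19 without triple-mutant replicate 3, and 217 with a replicate block, 165 higher and 52 lower. Equal sums gave 1 and 6 and moved the median of all genes by -0.116.

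A score of genes that responded to gcn5-7 in the other experiment placed libraries on a single scale. In B, with 9 rising and 12 falling genes chosen in A, the score was -2.88 ± 0.31 (SD, n = 5) in Col-0, 2.57 ± 0.56 in gcn5-7, -2.84 ± 0.40 in nrp1-1 nrp2-2 and -0.46 ± 0.64 in the triple mutant. The triple mutant differed from gcn5-7 by -3.03, lower in 5 of 5 replicate numbers, and from nrp1-1 nrp2-2 by 2.38. Exact p was 0.00794 each, the smallest possible with pairs ignored. Within replicates 1 and 2 the difference to gcn5-7 was -3.12 and within replicates 3 to 5 it was -2.96, where the smallest exact p is 0.333 and 0.1. The score of nrp1-1 nrp2-2 differed from Col-0 by 0.04 (exact p = 0.857). In A, with 1052 rising and 1272 falling genes chosen in B, the score was -2.77 ± 1.53 (n = 2) in Col-0, -0.66 ± 0.62 (n = 3) in gcn5-7, -3.02 ± 0.75 (n = 3) in arp6-1 and -1.18 ± 0.16 (n = 3) in the double mutant. The double mutant differed from gcn5-7 by -0.51 (exact p = 0.4), by -0.86 and -0.26 without gcn5-7 replicates 1 and 2, and by -1.26 after the gene-length correction (exact p = 0.1, the smallest possible). In a design whose smallest p is 0.1, gcn5-7 differed from Col-0 by 2.11 (exact p = 0.1) and arp6-1 from Col-0 by -0.26 (exact p = 1). These differences were 1.02 and -1.34 without Col-0 replicate 1, and 3.19 and 0.83 without replicate 2.

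**Figure D4:**
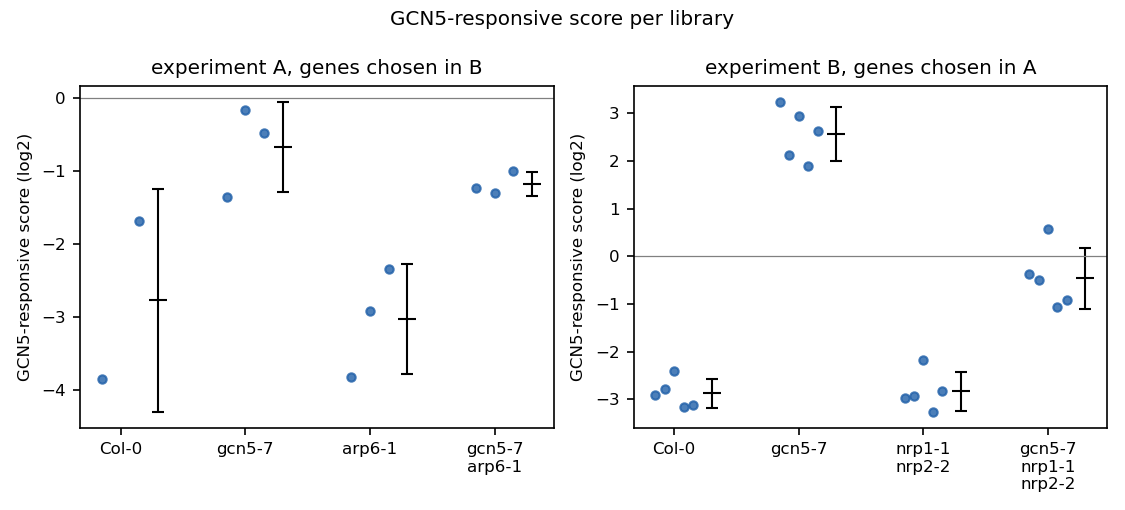
Score of gcn5-7-responsive genes (mean log2 level of genes that rose minus that of genes that fell) for each library, with the mean and SD of each group, in A with genes chosen in B and in B with genes chosen in A. In B the triple mutant lies at -0.46.

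Overlaps asked whether the mutants alter the same genes. In A, gcn5-7 and arp6-1 shared 0 of 26 and 3 called genes. Fold changes correlated at r = 0.136 (rho = 0.104) across genes. The r = 0.6 simulated for shared Col-0 libraries alone is no baseline, since same-number libraries covaried. In B, gcn5-7 and nrp1-1 nrp2-2 shared 24 genes that rose and 5 that fell, against 6.7 and 2.64 expected, and moved 7 genes in opposite directions. With the replicate block they shared 107 and 23, against 63.48 and 21.4 expected, with 47 opposite. STZ, TEM2, DIC2, LBD37 and PHB1 rose in both mutants. Over all genes r was -0.073 (rho = -0.136) in B. The 20 splits of Col-0 left 2 or 3 libraries per comparison and can call fewer genes. They shared 2 genes in the median (0 to 12), with median r -0.186.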

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

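Tests of gene length and time of day for the first batch of A, interaction and score were chosen before seeing their results. The other tests in this part were chosen after seeing theirs.

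In A, replicate 1 of Col-0, gcn5-7 and arp6-1 stood apart from the other 8 libraries, and a batch term called 12922 genes between them, 5272 higher and 7650 lower. Depth does not account for this, since the mean depth of the 3 libraries was 0.98 of that of the others. Gene length is not the whole cause either, as 54.2% of those genes remained called in the same direction after the gene-length correction. The clock list cannot decide on time of day at harvest. Its median size of the batch coefficient, 0.59, lay at percentile 49.8 of 10000 random lists of similar expression, but ignores direction. Time of day, growth and library preparation stay open, since the labels give no date or batch.

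In B, genes that responded to gcn5-7 in A lay nearer to Col-0 in the triple mutant than in gcn5-7, with a score difference of -3.03, or -1.91 without AT1G64795, AT1G75945 and AT2G11405 (exact p = 0.0159), which were higher in each gcn5-7 library of B than in any other. Chosen anew after the gene-length correction, 80 rising and 104 falling genes gave -1.965 (exact p = 0.0159), which argues against a trend with length. Seedlings with normal NRP2 mixed into the triple-mutant libraries would have to make up 55.6% and bring 435 NRP2 reads, where 0 were found. For nrp1-1 nrp2-2 seedlings with normal GCN5, the share needed was 72.8% in the median for the 9 rising genes and 19.6% for the 12 falling genes (permutation p = 0.00045), so that no single share fits both if pure triple-mutant seedlings had gcn5-7 levels. A lesser effect of the GCN5 mutation where NRP1 and NRP2 are lost may be proposed as a hypothesis.

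In A, 2504 genes differed between gcn5-7 arp6-1 and gcn5-7, with long genes higher in the double mutant. The trend with gene length is not the whole cause, since 63.4% of the called genes remained called in the same direction after the gene-length correction, and neither is the first batch, without which 98.8% remained. After that correction fewer remained for the double mutant against arp6-1 (925 of 2715) and Col-0 (141 of 378) and for the interaction (95 of 252). Separate preparation or handling of the double-mutant libraries and an effect of both mutations cannot be told apart, because 0 of the other 8 libraries had a correlation with gene length within the range of the double mutant (0.642 at its lowest, against 0.559 in the highest other library).

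Other splits of the same libraries were counted for each comparison with groups of at least 3. For the double mutant against gcn5-7 and against arp6-1 in A the 10 splits are too few for a share under 0.05, with real counts of 2504 and 2715 (1 split as large, the real one, in each) and 0 genes in the highest other split. In B, 100 splits were drawn of 126 possible. Chance was unlikely for gcn5-7 (5118 genes, 1 split as large, highest other 2364). It stayed open for the interaction (8 genes, 1 split, highest other 0). Within replicate numbers, 3 of 100 splits were as large (highest other 1176), and single-mutation effects enter both shuffles. In the comparisons where replicates are paired, the counts were 474 for the triple mutant (1 split, highest other 2), 627 for it against gcn5-7 (2 splits, highest other 1879), 139 against nrp1-1 nrp2-2 (5 splits, highest other 4446) and 76 for nrp1-1 nrp2-2 (4 splits, highest other 6388). Among the 12 to 14 splits drawn for each that part all 5 pairs, as the real one does, the highest other was 2 for the triple mutant and 0 for the rest, and these are too few for a share under 0.05. The split that called 6388 genes placed replicates 1 and 2 of Col-0 with replicates 1, 2 and 3 of nrp1-1 nrp2-2, and calls many times the real count, which points to a structure of the samples by replicate number. Within replicates 3 to 5 the counts were 89 for nrp1-1 nrp2-2, 145 for the triple mutant against gcn5-7 and 24 for it against nrp1-1 nrp2-2, and within replicates 1 and 2 they were 7, 215 and 23.

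Among groups of 5 libraries in B, 16 values stood far from the other 4 of their group, of 32 group values of library measures and 252 of named genes, where chance gives about 1 in 20. The share of chloroplast transcripts in nrp1-1 nrp2-2 replicate 1 was 0.55% (others 0.102 to 0.198%) and the share of mitochondrial transcripts in the same library was 0.0256% (others 0.00529 to 0.00983%). OSM34 was at 2.06 in Col-0 replicate 5 (others 0.08 to 0.433) and at 2.11 in nrp1-1 nrp2-2 replicate 3 (others 0.092 to 0.157). In Col-0 replicate 1, MAF3 was at 3.98 (others 7.91 to 9.38), NRP1 at 19.8 (others 27.8 to 31.3) and CHS at 809 (others 420 to 495). In gcn5-7 replicate 1, EXLB1 was at 0.091 (others 0), ARP6 at 8.79 (others 12.4 to 14) and TOM7-2 at 0.663 (others 2.82 to 3.46). In gcn5-7 replicate 2, GCN5 was at 6.78 (others 3.55 to 4.3). In gcn5-7 replicate 4, IAA17 was at 44 (others 24.4 to 27.9) and MCM7 at 15.68 (others 11.5 to 12.5). DIC2 was at 50.5 in nrp1-1 nrp2-2 replicate 2 (others 22.9 to 27.9). In triple-mutant replicate 3, AGP41 was at 1.64 (others 5.2 to 7.52) and XTH31 at 2.43 (others 10.6 to 15.6).

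The interaction test called 252 genes in A, where separate handling of the double mutant stays open, and 8 in B. The named ones in A were ATSPS4F at 4.43, SS4 at 4.38, CFM3A at 4.36, ZW9 at 4.06, FMO GS-OX2 at 3.88, EXO at -4.5, ARD3 at -4.11 and TCH4 at -3.76. In B they were PGL34 at 1.98 and FUC1 at 1.7.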

How the results depend on the processing

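Batch terms, batches left out, replicate subsets, gene-length correction, voom and libraries left out of list tests were chosen after seeing the data. In each alternative on all 5 replicates, the score difference of triple mutant and gcn5-7 in B kept its direction and side of the threshold (-1.42 to -8.47). At -8.47 (mean of at least 5) the score held 1 rising and 4 falling genes. Within replicates 1 and 2 and within 3 to 5 the difference kept its direction, as did that in A (-0.24 to -1.26). The smallest exact p there is 0.333, 0.1 and 0.1. The correlation of gcn5-7 between A and B was 0.645 to 0.766. Counts of called genes changed far more, and the cause was not tested except where fewer genes or fewer libraries entered a test. Experiment A is limited by 2 Col-0 libraries and its first batch. Genes with a mean below 1 were not tested, among them FLC in A, and replicates differed by more than sampling noise in each pair.

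The replicate block, which treats replicate numbers as pairs, gave 120 genes for gcn5-7, 9 for arp6-1, 2477 for the double mutant, 6952 for it against gcn5-7, 9117 against arp6-1 and 4533 for the interaction in A, with 1 gene shared by gcn5-7 and arp6-1. In B it gave 9714 for gcn5-7, 334 for nrp1-1 nrp2-2, 1787 for the triple mutant, 4953 for it against gcn5-7, 1237 against nrp1-1 nrp2-2 and 217 for the interaction, with 130 shared by gcn5-7 and nrp1-1 nrp2-2. With gene-length correction added, the replicate block gave 358, 18, 961, 5460, 5537 and 1956 in A and 9583, 525, 2303, 5050, 1384 and 485 in B, in the same order.

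The batch term in A gave 1468 genes for gcn5-7, 161 for arp6-1, 2514 for the double mutant, 7445 for it against gcn5-7, 8470 against arp6-1 and 6595 for the interaction, with 25 shared by gcn5-7 and arp6-1. With gene-length correction added these were 2191, 164, 1445, 6664, 5301 and 4245, and with the first batch left out 81, 55, 718, 7517, 9751 and 7217. Under the batch term NRP1 in the double mutant against Col-0 turned to -0.72 (adjusted p = 0.0478). In B a batch term gave 7956 for gcn5-7, 151 for nrp1-1 nrp2-2, 892 for the triple mutant, 2139 for it against gcn5-7, 336 against nrp1-1 nrp2-2 and 31 for the interaction. Replicates 3 to 5 alone gave 2345 for gcn5-7, 145 for the triple mutant against gcn5-7, 24 against nrp1-1 nrp2-2 and 2 for the interaction. Replicates 1 and 2 alone gave 7 for nrp1-1 nrp2-2, 5 for the triple mutant, 215 and 23 for it against gcn5-7 and nrp1-1 nrp2-2, and 2 for the interaction. Fewer libraries enter these last fits.

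The gene-length correction gave 202 for gcn5-7 in A, 16 for arp6-1, 1350 for the double mutant against arp6-1, 151 for nrp1-1 nrp2-2, 956 for the triple mutant against gcn5-7 and 18 for the interaction in B, with 1 gene shared in A and 69 in B. It turned TRA1B in gcn5-7 of B to -0.22 (adjusted p = 0.387), as it did together with the replicate block (-0.22, adjusted p = 0.174). Equal library sums without organelle genes gave 16 for gcn5-7 in A, 39 for the interaction in A and 30 for nrp1-1 nrp2-2, with 1 gene shared in A and 15 in B. Quantile normalization gave 49 for gcn5-7 in A, 5 for arp6-1, 811 for the double mutant, 3845 and 4662 for it against gcn5-7 and arp6-1, 774 for the interaction in A, 1246 for the triple mutant against gcn5-7 and 14 for the interaction in B. Voom on recovered reads gave 44 for gcn5-7 in A, 42 for the double mutant, 1751 for it against arp6-1 and 33 for the interaction in A.

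A mean of at least 5, which tests fewer genes, gave 5 for gcn5-7 in A, 1 for arp6-1, 11 for the double mutant, 745 and 391 for it against gcn5-7 and arp6-1 and 2 for the interaction in A. In B it gave 47 for nrp1-1 nrp2-2, 252 for the triple mutant, 378 and 46 for it against gcn5-7 and nrp1-1 nrp2-2, 5 for the interaction and 19 shared genes. No filter gave 40 for gcn5-7 in A, 909 for the double mutant, 565 for the interaction in A and 25 in B. Only the groups compared, with fewer libraries in the fit, gave 0 for gcn5-7 in A, 0 for arp6-1, 0 for the double mutant, 4913 and 7692 for it against gcn5-7 and arp6-1, 11 for nrp1-1 nrp2-2 and 30 for the triple mutant against nrp1-1 nrp2-2. Plain empirical Bayes gave 180 for the double mutant and 87 for the interaction in A. A pseudocount of 0.1 gave 61 for gcn5-7 in A, 5 for arp6-1, 69 for the double mutant, 1737 for it against arp6-1, 15 for the interaction in A and 1 gene shared in A. A pseudocount of 5 gave 17, 1, 924 and 750 for gcn5-7, arp6-1, the double mutant and the interaction in A. Of 276 list tests 92 were called at the preset correlation and 3 with the estimated one.

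Leaving out 1 library at a time gave 3 to 90 genes for gcn5-7 in A, 0 to 9 for arp6-1, 17 to 7216 for the double mutant, 414 to 2682 for it against gcn5-7, 313 to 2607 against arp6-1 and 0 to 2980 for the interaction. In B it gave 2949 to 5878 for gcn5-7, 36 to 121 for nrp1-1 nrp2-2, 326 to 515 for the triple mutant, 183 to 1652 for it against gcn5-7, 90 to 176 against nrp1-1 nrp2-2 and 6 to 19 for the interaction. Where this left a single Col-0 library in A, it was assumed to vary like the other groups. Of the named genes called, 29 of 71 for gcn5-7 in B kept their call under each setting run and 54 with each library left out. For the others, in the order of this paragraph, these were 0 and 1 of 7, 0 and 0 of 2, 0 and 5 of 20, 7 and 5 of 10, 8 and 3 of 10 and 2 and 0 of 8 in A. In B they were 1 and 6 of 11, 2 and 13 of 18, 5 and 7 of 10, 1 and 5 of 9 and 0 and 1 of 2. Of the 92 list calls, 43 held in each run with a library left out. For floral organ identity in nrp1-1 nrp2-2 and in the triple mutant against it, 6 of 10 runs had the 5 members needed. In A these were defence in gcn5-7, floral organ identity and heat shock in arp6-1, DNA damage, acetylation and light harvesting in the double mutant and acetylation for the interaction. Against gcn5-7 all but FLC clade and phosphate held, and against arp6-1 all but light harvesting. In B they were defence, light harvesting, flavonoids, acetylation, DNA damage and floral organ identity in gcn5-7, the latter and FLC clade in nrp1-1 nrp2-2, and FLC clade, flavonoids and cold and ABA in the triple mutant. Against gcn5-7 all but auxin, flavonoids, FLC clade, flowering time and iron held, against nrp1-1 nrp2-2 all but defence, and for the interaction all but DNA damage, glucosinolates, heat shock and iron. Each alternative chosen before the data were examined was run. In the comparisons where replicates are paired, the replicate block changed no call of a named gene or list test other than those given with the comparisons.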

Other observations

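All tests in this part were chosen after the results that prompted them were seen. In nrp1-1 nrp2-2 of B, nuclear genes for mitochondrial import, folding and prohibitins were higher as a group than in Col-0 (n = 5 each). Of 25 measured members, 7 rose and 0 fell over all genes tested (11 and 0 adjusted over the list alone), with a median log2 fold change of 0.52 and 22 above 0 (camera p = 2.25e-21, and 0.000106 with an estimated correlation). In the triple mutant 10 members rose (13 adjusted over the list alone; median 0.62, camera p = 6.09e-14, and 0.000961 with an estimated correlation). Against gcn5-7 the triple mutant had 5 members that rose (6 adjusted over the list alone; median 0.30, camera p = 0.00021, and 0.0639 with an estimated correlation), and gcn5-7 itself had 8 that rose and 1 that fell (8 and 1 adjusted over the list alone; median 0.28, camera p = 0.00899, and 0.18 with an estimated correlation).

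Loss of NRP1 and NRP2 may raise these genes as a group, as a hypothesis, since the list was written after the prohibitin genes had been seen. The 18 members that were not called had a median of 0.28, with 15 above 0 (camera p = 2.56e-06, and 0.00303 with an estimated correlation), a test that could have come out at 0. Markers of mitochondrial dysfunction were not higher as a group (camera p = 0.948, and 0.968 with an estimated correlation). Over their 13 measured members the median log2 fold change was -0.1, and the 1 called gene, over all genes and adjusted over the list alone, was DIC2 (1.89).

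RNA from the mitochondrial genome was lower in both NRP mutants of B. Its share of the signal was 0.0108 ± 0.0085% (SD, n = 5) in nrp1-1 nrp2-2 and 0.0169 ± 0.01% in the triple mutant against 0.0458 ± 0.015% in Col-0 (exact p = 0.00794 each, the smallest possible, and 0.0397 after Benjamini-Hochberg adjustment over 10 comparisons), lower in 5 of 5 replicate numbers. The share in gcn5-7 was 0.0399 ± 0.013%, from which the triple mutant differed with exact p = 0.0159 (0.053 adjusted), lower in 5 of 5. The triple mutant was higher than nrp1-1 nrp2-2 in 5 of 5 (exact p = 0.214). In A the share was 0.0112 ± 0.0055% (n = 3) in the double mutant, 0.0582 ± 0.0024% (n = 2) in Col-0, 0.0729 ± 0.025% in gcn5-7 and 0.042 ± 0.018% in arp6-1 (exact p = 0.1 for the double mutant against each, the smallest possible).

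Genes that responded to nrp1-1 nrp2-2 were followed into the gcn5-7 background. A score of 58 rising and 15 falling genes chosen against Col-0 stood at -1.01 ± 0.21 in Col-0, -0.11 ± 0.19 in gcn5-7, 2.11 ± 0.07 in nrp1-1 nrp2-2 and 1.71 ± 0.28 in the triple mutant (SD, n = 5). The triple mutant exceeded gcn5-7 by 1.82 (exact p = 0.00794), and 70 of the 73 genes moved with the same sign as in nrp1-1 nrp2-2. These genes may thus move in the same direction on loss of NRP1 and NRP2 where GCN5 is mutated, while the sizes of the change were not tested against each other.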
